A study of Gossypium barbadense and Gossypium hirsutum with 2 samples.

How the data were processed

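Total RNA of fibers detached from ovules of field-grown plants 10 days post-anthesis was size-selected on a denaturing polyacrylamide gel, ligated to adaptors, amplified by RT-PCR and sequenced on a Solexa (Illumina) instrument, per the labels' protocols. The cultivars 3-79 and TM-1 had 1 library each. Groups were taken from the cultivar named in the labels.

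The deposited values were raw read counts per distinct sequence tag. One table had a header naming length, number and sequence, and the other had no header and was read by its values, which had the same layout. Every tag was 18 to 30 nt long and none was listed more than once. Base calling, adaptor trimming and quality filters are not given in the sources used here, so reads removed before deposit cannot be counted. Size selection on the gel and adaptor ligation favor some lengths and sequences, so levels of different miRNAs in a library are compared less safely than the same miRNA between libraries. No molecular identifiers were described, and PCR copies count as separate reads.

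Counts were scaled to RPM of all deposited reads. A tag of 19 to 24 nt was counted to a family when it held positions 3 to 18 of a listed sequence without mismatch and started within 2 nt of its 5′ end. The 56 listed sequences, of which 11 were passenger strands, were written from general knowledge of mature plant miRNAs, mostly of Arabidopsis, before the data were examined, and were not checked against a database. A family absent here can therefore be present in a cotton form that differs from the listed sequence. No genome sequence was used here, so tags were not placed in a genome, no coordinates are given, and the homoeologous copies of a family in these tetraploid species were counted together.

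Shares carry exact Clopper-Pearson intervals, levels exact Poisson intervals and ratios exact conditional binomial intervals, all at 95%. These intervals and the floor of 3 counts for an observed 0 cover counting error only. A family was listed as different when the libraries together held at least 100 reads, the ratio was at least 2 and its interval left out 1. This is a rule of size and not a test between cultivars. Tags of 20 to 22 nt were treated alike with a ratio of at least 4. The median log2 ratio of each of 8 family lists, with a prior count of 0.5 and over members with at least 10 reads, was ranked among 10000 random lists of tags matched on abundance. Those were single tags outside the listed families, while a family sums its tags, so the percentiles are descriptive. Short lists had wide random ranges, as from -7.65 to 6.61 for the disease resistance list, and their percentiles say little. Structural RNA reads were those within 2 rRNA or 3 tRNA sequences.

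The families named are the 10 with the highest mean RPM, the up to 10 with the largest log2 ratio in either direction among those with at least 100 reads, every listed family, the 2 to 4 most abundant members of each list, and the 3 unnamed 20 to 22 nt tags most raised in each library. These rules, the sequences, the lists and the alternatives other than the added one were fixed before the data were examined. The unnamed tags are given by length and reads without sequence, since their origin is not settled without a genome. The miR167 end forms, the miR172-like and miR535-like tags and the most abundant unlisted tag were chosen after their values were seen. The family miR2111 was added after the listed families had been examined and before its own reads were. One alternative, leaving tags of 1 library out of the totals, was also added after the data were examined.

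The interval and the 4-fold rule were tested on simulated Poisson counts for the 1345 tags of 20 to 22 nt, using their real means and the real library sizes. All 100 tags changed 8-fold were listed, and none of the 100 changed 2-fold and none of the 1145 unchanged tags were. The intervals held the true ratio for 95.5% of unchanged tags. These counts contained no variation between plants, and the intervals are built for such counts, so this checked the calculation only. The 2-fold rule for families was not simulated.

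The alternatives were other scalings (reads of 18 to 26 nt, reads of the listed families, a trimmed mean of 20 to 22 nt tags), matching by identity or with 1 mismatch, minimums of 10 or 1000 reads, a ratio of 1.5, thinning TM-1 to the depth of 3-79, and leaving out tags with 1 read. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.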

Results

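Small RNAs were sequenced from cotton fibers collected 10 days post-anthesis from 2 cultivars, the sea-island cotton 3-79 (Gossypium barbadense) and the upland cotton TM-1 (Gossypium hirsutum). A cotton fiber is a single elongated cell of the ovule surface, and the study asked which miRNAs differ between the species during fiber elongation. The data were 1 library per cultivar, with 7764225 reads of 4863589 distinct tags in 3-79 and 7839450 reads of 4983793 distinct tags in TM-1. Tags with 1 read made up 86.7% of the distinct tags of 3-79 and 87.0% of those of TM-1. A count of 0 was taken to allow up to 3 counts, or 0.386 RPM (reads scaled to a library of 1000000 reads) in 3-79 and 0.383 RPM in TM-1. The exact 95% interval of a count of 0 reaches further, to 0.475 RPM in 3-79 and 0.471 RPM in TM-1. With 1 library per cultivar there was no replicate check, so no difference could be set against a spread between replicates and no p-value is given. Ranges in parentheses are exact 95% intervals, which cover counting error of these libraries only.

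Both libraries were dominated by 24 nt RNAs, the length typical of plant siRNAs. Smaller classes lay at 23 nt, with 14.37% of the reads of 3-79 and 15.26% of those of TM-1, and at 21 nt, the usual length of plant miRNAs. Reads of 24 nt made up 48.8% of 3-79 (48.77 to 48.84%) and 49.8% of TM-1 (49.80 to 49.87%). Reads of 21 nt made up 14.2% of 3-79 (14.19 to 14.23%) and 13.3% of TM-1 (13.26 to 13.31%). The ratio of 24 nt to 21 nt reads was 3.43 in 3-79 (3.43 to 3.44) and 3.75 in TM-1 (3.74 to 3.76). Without the 100 most abundant tags of each library the ratios were 5.43 and 5.71. Among 21 nt reads, T was the first base of 55.8% in 3-79 and 54.7% in TM-1, and these shares were 36.0% and 37.4% without the 10 most abundant tags. Among 24 nt reads, A was the first base of 41.5% in 3-79 (41.49 to 41.59%) and 38.5% in TM-1 (38.50 to 38.59%).

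**Figure D1:**
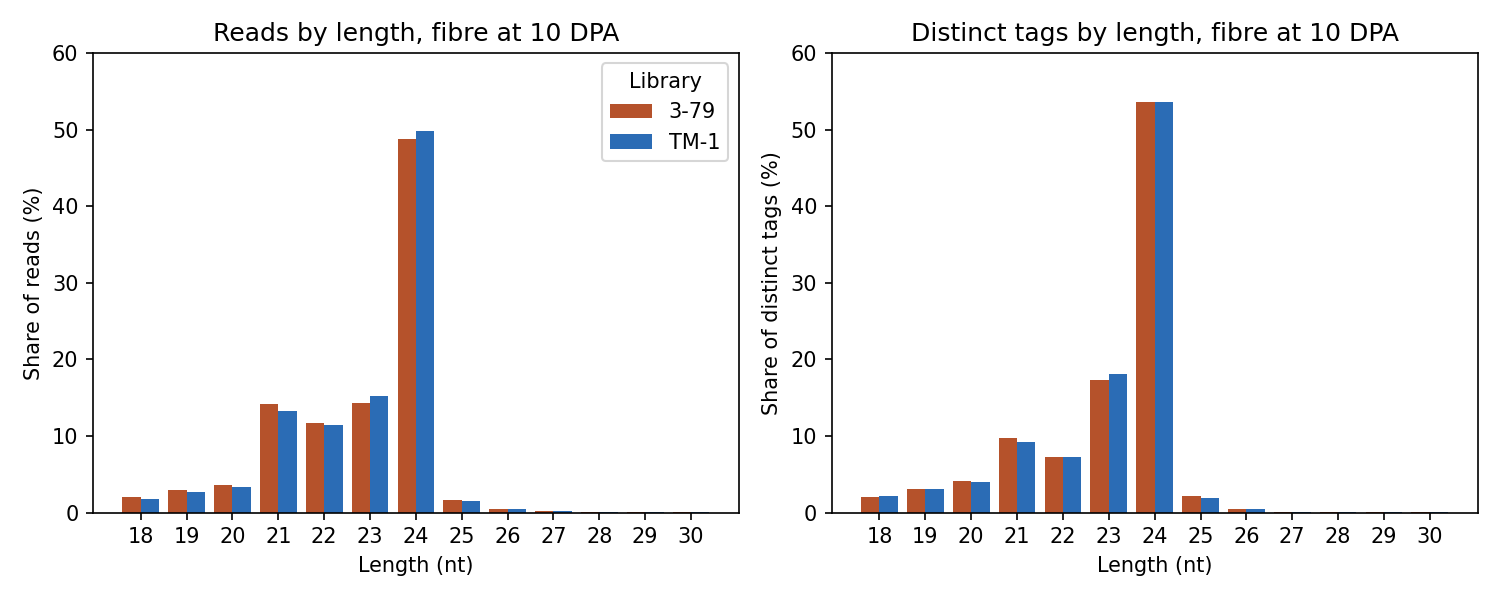
Share of reads (left, percent) and of distinct tags (right, percent) at each length from 18 to 30 nt, with 1 bar per library. Reads of 24 nt form the highest bar in both libraries, at 48.8% in 3-79 and 49.8% in TM-1, and 21 nt reads stand at 14.2% and 13.3%.

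The listed miRNA families, without tasiR-ARF, which is not a miRNA, held 6.90% of the reads of 3-79 (6.88 to 6.92%) and 5.68% of those of TM-1 (5.66 to 5.69%). The shares were 1.88% and 1.33% with identical tags, and 15.1% and 12.7% without tags of 1 read. Of 39 families searched, tasiR-ARF among them, 33 had reads, and 25 had at least 100 reads in the libraries together. At least 2-fold higher in 3-79 were 3 families, at least 2-fold higher in TM-1 were 2, and 20 lay within 2-fold. Scaled to the reads of the listed families, which shifted every log2 ratio by -0.28, the split was 2 and 4. The trimmed mean of 20 to 22 nt tags shifted ratios by 0.015 and left the split at 3 and 2.

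The families higher in 3-79 were miR827, miR399 and miR408. Families miR827 and miR399 act in phosphate homeostasis, where they target SPX-domain protein and PHO2 transcripts, and miR408 targets transcripts of plantacyanin and laccases. Family miR827 had 166 reads in 3-79 and 8 in TM-1, a ratio of 20.95 (10.4 to 49.3). Family miR399 had 606 and 89 reads, a ratio of 6.87 (5.50 to 8.69). Its most abundant tag, TGCCAAAGGAGATTTGCCCGG, gave 519 of the reads in 3-79 and 62 in TM-1. Family miR408 had 187 and 89 reads, a ratio of 2.12 (1.64 to 2.76). Ranked among 200 single tags of like abundance, the ratios stood at percentile 85.5 for miR827, 93.0 for miR399 and 79.5 for miR408. A high percentile leans toward 3-79. Some tags of like abundance thus leaned at least as far toward 3-79 as each of these families, and the percentiles are descriptive. The ratio of miR408 fell under 2-fold when scaled to the listed families (log2 0.80) and with 1 mismatch allowed (1.98). When tags had to be identical to a listed sequence, miR399 (17 and 12 reads) and miR827 (2 and 1 reads) left the list, since their most abundant tags were not identical to a listed sequence.

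The families higher in TM-1 were miR165, which targets transcripts of class III HD-ZIP transcription factors, and miR393, which targets the TIR1/AFB auxin receptor transcripts. Family miR165 had 40 reads in 3-79 and 108 in TM-1, so that TM-1 was 2.67-fold higher (1.84 to 3.95). Its sequence is the T17C form of the far more abundant miR166 tag, with positions counted from 1 at the 5′ end. The identical miR165 tag stood at 0.358% of the miR166 tag in 3-79 and 0.484% in TM-1. Of the 62 other single-base forms of miR166, 12 in 3-79 and 9 in TM-1 were as abundant, so miR165 reads could not be separated from substituted miR166 reads. Family miR393 had 63 and 129 reads, 2.03-fold higher in TM-1 (1.49 to 2.79). With 1 mismatch allowed, TM-1 was 1.99-fold higher and it left the list. With identical tags, miR165 (25 and 63 reads) and miR393 (3 and 10 reads) both left the list, under the minimum of 100 reads.

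**Figure D2:**
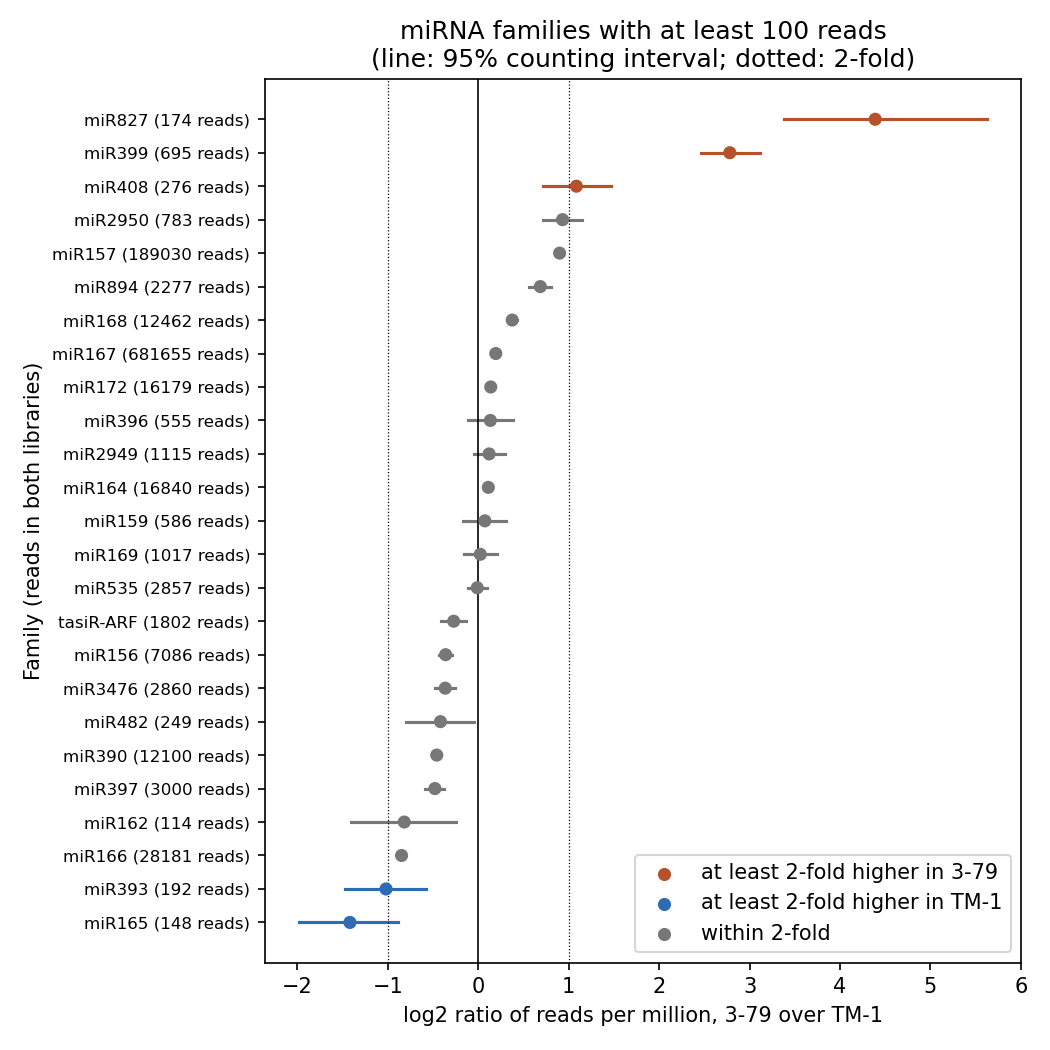
Log2 ratio of RPM, 3-79 over TM-1, for the 25 families with at least 100 reads; points are ratios, lines are 95% counting intervals and dotted lines mark 2-fold. The miR827 (4.39), miR399 (2.78) and miR408 (1.09) points lie beyond 2-fold toward 3-79, though miR408 falls to 0.80 when scaled to the listed families. The miR165 (-1.42) and miR393 (-1.02) points lie beyond it toward TM-1.

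The most abundant family in both libraries was miR167, which targets the auxin response factors ARF6 and ARF8. It stood at 46627 RPM in 3-79 and 40773 RPM in TM-1, or 67.6% and 71.8% of the reads of the listed families. Its ratio of 1.14 (1.138 to 1.149) turned to a log2 ratio of -0.09 when scaled to the listed families, a total that is mostly miR167 itself. With identical tags, only 453 and 961 reads, it turned to -1.07. Its passenger strand, the other arm of the duplex, had 1624 and 746 reads, a ratio of 2.20 (2.01 to 2.40). Second was miR157, which targets SPL transcription factors, at 15796 and 8468 RPM, a ratio of 1.87 (1.85 to 1.88). The related miR156 stood at 397 and 510 RPM, a ratio of 0.779 (0.743 to 0.816). Thus miR157 made up 97.5% of miR156 and miR157 reads in 3-79 and 94.3% in TM-1. Family miR166 was 1.80-fold higher in TM-1 (1.76 to 1.85), at 1288 RPM in 3-79 and 2319 RPM in TM-1, and reached a log2 ratio of -1.13 when scaled to the listed families. Outside the lists, miR894 stood at 180 and 112 RPM, a ratio of 1.61 (1.48 to 1.75). With identical tags it had only 3 and 0 reads. Its most abundant tag started 1 nt from the listed 5′ end and held only 26.2% of its reads in 3-79 and 26.4% in TM-1.

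Among the 5 auxin signalling members, 1 of the 4 with at least 100 reads, miR393, was listed as higher in TM-1 and 3 were not listed. Unlisted were miR167, miR390, which triggers the TAS3 pathway, and its product tasiR-ARF. The miR390 level was 653 RPM in 3-79 and 897 RPM in TM-1, a ratio of 0.727 (0.702 to 0.754). The tasiR-ARF level was 105 and 126 RPM, a ratio of 0.828 (0.754 to 0.910). Its log2 ratio was -1.23 with identical tags, on 32 and 76 of its 812 and 990 reads. The list's median log2 ratio was -0.27, at percentile 55.1 of 10000 random lists of tags matched on abundance, and was -1.07 with identical tags.

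Among developmental transcription factor regulators, 9 of 12 had at least 100 reads, of which miR165 was listed as higher in TM-1 and 8 were not listed. The NAC regulator miR164 stood at 1121 and 1038 RPM, a ratio of 1.08 (1.05 to 1.11), and the AP2 regulator miR172 at 1087 and 988 RPM, a ratio of 1.10 (1.07 to 1.13). Both ratios turned below 1 when scaled to the listed families, at log2 -0.17 and -0.14. The miR172 log2 ratio was -0.47 with identical tags and 0.69 with 1 mismatch allowed. The list's median was 0.07, at percentile 76.2, and turned to -0.21 when scaled to the listed families and to -0.16 with identical tags.

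Both nutrient families with at least 100 reads, miR399 and miR827, were higher in 3-79. The sulfate regulator miR395 had 46 and 45 reads, a ratio of 1.03 (0.669 to 1.59). The list's median log2 ratio was 2.77, at percentile 96.0, inside the range of -4.37 to 5.06 that held 95% of random lists. With identical tags the median was 0.24. Of the copper and laccase list, miR408 was higher in 3-79, miR398 had no reads, and miR397 was not listed. The laccase regulator miR397 stood at 160 and 224 RPM, a ratio of 0.717 (0.666 to 0.772). That list's median was 0.30, at percentile 69.4.

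None of the 2 small RNA pathway families with at least 100 reads was listed, and the list's median log2 ratio was -0.55, at percentile 39.4. The Argonaute 1 regulator miR168 stood at 902 and 696 RPM, a ratio of 1.30 (1.25 to 1.34). The Dicer-like 1 regulator miR162 had 41 and 73 reads, a ratio of 0.567 (0.377 to 0.843), and was listed as higher in TM-1 when scaled to the listed families. Of the disease resistance gene regulators only miR482 had reads, 106 and 143, a ratio of 0.748 (0.577 to 0.969), with a list median of -0.42 at percentile 49.3. With 1 mismatch allowed, miR2118 had 0 reads in 3-79 and 30 in TM-1.

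For the MYB list the median log2 ratio was 0.85, at percentile 73.2, over 2 members, and it turned to -0.16 with identical tags, where 1 member was left. The GAMYB regulator miR159 had 299 and 287 reads, a ratio of 1.05 (0.892 to 1.24). The R2R3 MYB regulator miR858 had 38 and 12 reads, under the minimum of 100, a ratio of 3.20 (1.64 to 6.72). With 1 mismatch allowed it had 210 and 46 reads, a ratio of 4.61 (3.34 to 6.49), and was listed. Of the families described first in cotton or other rosids, none of the 3 with at least 100 reads was listed, and the median was 0.12 at percentile 71.2. It turned to -0.16 when scaled to the listed families and to -0.12 with 1 mismatch allowed. Their levels were 65.9 and 34.6 RPM for miR2950, a ratio of 1.91 (1.64 to 2.22), 160 and 206 RPM for miR3476, a ratio of 0.776 (0.720 to 0.836), and 74.4 and 68.5 RPM for miR2949, a ratio of 1.09 (0.965 to 1.22).

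The miR167 family differed between the libraries in its end more than in its amount, a feature chosen after its values were seen. Among reads of the 21 nt miR167 tags that differ only at position 21, 99.5% in 3-79 were TGAAGCTGCCAGCATGATCTT. In TM-1 this form held 46.0%, and its T21C form, TGAAGCTGCCAGCATGATCTC, held 53.5% (53.2 to 53.7%). The T21C form was 0.223% of such reads in 3-79 (0.204 to 0.245%), and TM-1 was 224-fold higher (204 to 246). In 3-79 the T21A form was about as frequent, at 0.218% (0.198 to 0.239%). The T21C reads of 3-79 could thus not be separated from substituted reads of the T form, and the fold rests on them. Among such 22 nt reads, all ending in A, the T21C form held 57.8% in TM-1 and 0.167% in 3-79, 275-fold higher in TM-1 (241 to 314). The T21A form held 0.0761% of them in 3-79. The form with T was 2.31-fold higher in 3-79 at 21 nt (2.29 to 2.33) and 3.00-fold higher at 22 nt (2.97 to 3.04).

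**Figure D3:**
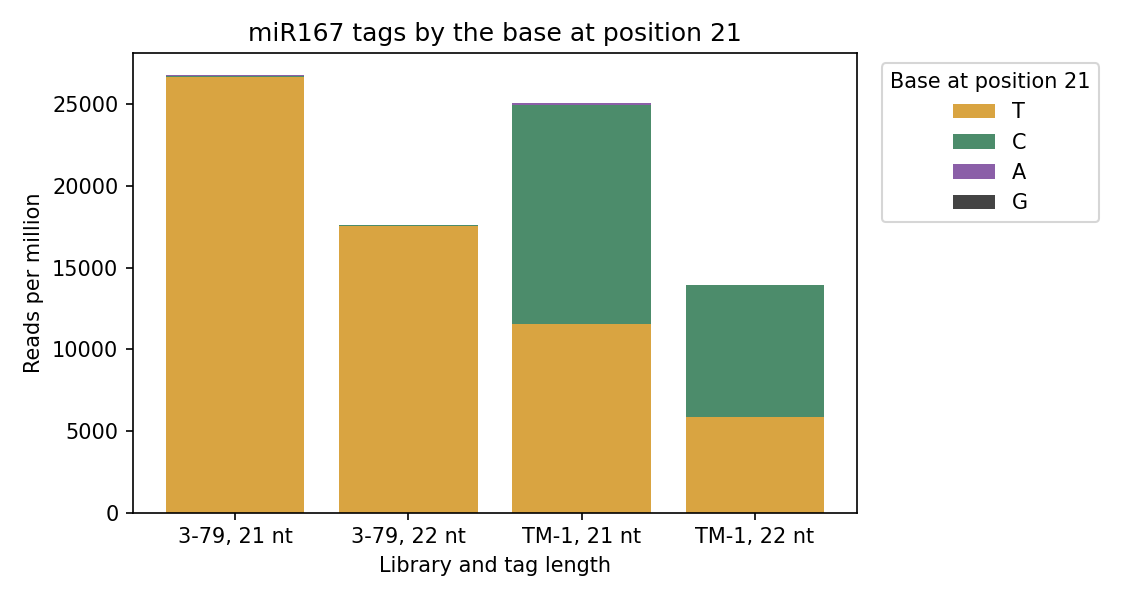
RPM of the miR167 tags of 21 nt and of 22 nt that differ only at position 21, counted from the 5′ end, in each library. Bars are divided by the base at that position. Nearly all of these reads in 3-79 carry T, and the T21C form holds 53.5% of those of 21 nt and 57.8% of those of 22 nt in TM-1.

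Most distinct tags were seen in 1 library. The libraries shared 644279 tags, 13.2% of those of 3-79 and 12.9% of those of TM-1, which held 37.0% and 36.1% of the reads. Without tags of 1 read the shared tags were 28.7% and 28.5%. Among 1345 tags of 20 to 22 nt with at least 100 reads, 204 were at least 4-fold higher in 3-79 and 233 in TM-1. Of the 233, 7 were miR167 tags. The unnamed tags most raised in 3-79 were all 22 nt long, with 3444, 1757 and 1386 reads against 4, 0 and 2 in TM-1. Those most raised in TM-1 had 955, 792 and 581 reads against 3, 2 and 2 in 3-79. In 3-79, 134 tags had at least 100 reads and none in TM-1, and 2.99% of them (0.819 to 7.47%) had a partner, a tag of the same length 1 base away with at least 10 reads in TM-1 and none in 3-79. In TM-1, 69 tags had at least 100 reads and none in 3-79, and 2.90% (0.353 to 10.1%) had such a partner. The shares for tags seen in both libraries and matched on abundance were 5.97% and 0%, the latter of 69 tags with an upper bound of 5.21%. At a minimum of 20 reads, the shares with a partner were 5.98% in 3-79 (4.96 to 7.14%) and 6.91% in TM-1 (5.84 to 8.11%), above the 2.97% (2.25 to 3.83%) and 0.995% (0.609 to 1.53%) of matched tags. With partners of at least 2 reads, the shares were 4.48% in 3-79 and 7.25% in TM-1. Matched tags then had 65.7% and 46.4%. This is no comparison, since 1-base copies of tags present in the other library count as partners.

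Fragments of the 2 rRNAs and 3 tRNAs searched were a small part of both libraries. They were larger in TM-1 for the rRNAs together and for the tRNAs together. Other structural RNAs were not searched. Reads within 5.8S and 5S rRNA made up 0.166% of 3-79 and 0.237% of TM-1, 1.43-fold higher in TM-1 (1.40 to 1.46). Taken alone, 5S rRNA was higher in 3-79, with a ratio of 1.87 (1.72 to 2.04). Reads within 3 tRNAs made up 0.122% and 0.192%, 1.57-fold higher in TM-1 (1.53 to 1.61).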

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

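The results here were picked because reads appeared outside the listed sequences, above what a count of 0 allows; the tests of this part were chosen after the result was seen.

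The most abundant tag without a listed name, TTGGACAGAGTAATCACGGTCG, was 22 nt long. It had 201192 reads in 3-79 (2.59%) and 188858 in TM-1 (2.41%), a ratio of 1.08 (1.07 to 1.08), and was outnumbered among the listed families only by miR167. Reads that start with the first 18 bases of the animal miRNA let-7 numbered 36 in 3-79 (4.64 RPM, 3.25 to 6.42) and 28 in TM-1 (3.57 RPM, 2.37 to 5.16).

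Tags with at least 100 reads in 1 library and none in the other held 32961 reads in 3-79 and 11350 in TM-1. A single-base difference that replaced a tag wholly would leave most of the 3-79 tags with a partner 1 base away in TM-1. A partner of at least 10 reads there and none in 3-79 was found for 2.99% (0.819 to 7.47%). This argues against such differences as the general cause. The search missed tags whose TM-1 form also occurred in 3-79 and tags that differ by more than 1 base. Base differences of those kinds stay open. At a minimum of 20 reads 5.98% had a partner, above the 2.97% of matched tags. A wholly replaced base thus stays open for a small part of these tags. With partners of at least 2 reads 4.48% had one. The 65.7% of matched tags is no comparison there, since those tags are present in TM-1 and their own 1-base copies count as partners. RNA from another organism or source in the 3-79 library is a candidate explanation, since 58.4% of the reads of these tags were 18 to 20 nt long, against 2.10% for the TM-1 tags. At a minimum of 20 reads the shares were 35.3% in 3-79 and 1.07% in TM-1. The 35.3% was under the 50% set for that explanation. The limits, and the need to meet them at both minimums, were set after the lengths were seen. Such outside RNA cannot be told apart from loci expressed or present in sea-island cotton alone, because the tags were not placed in a genome. The difference between the species stays open and untested.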

How the results depend on the processing

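No paired analysis was possible because the groups share only 1 replicate number and no result comes from a test. Leaving tags of 1 library out of the totals was chosen after seeing the data. The 3 families listed as higher in 3-79 and the 2 in TM-1 were the same families when scaled to reads of 18 to 26 nt, by trimmed mean, with TM-1 thinned, without tags of 1 read and without tags of 1 library in the totals. Scaled to the listed families, 2 were higher in 3-79 and 4 in TM-1. With identical tags, 1 was higher in 3-79 (miR408) and 2 in TM-1, neither among the main 2. These were miR167 (453 and 961 reads) and tasiR-ARF (32 and 76 reads), each on a small part of its family's reads. Log2 ratios were then -1.32 for miR165 (25 and 63 reads) and -1.72 (-4.22 to 0.23) for miR393 (3 and 10 reads), both under the minimum of 100 reads; the listed miR167 sequence carries the T21A base, which few reads have. With 1 mismatch, 3 were higher in 3-79 and 1 in TM-1. At 1000 reads 0 and 0 were listed, since each family listed as higher in the main setting had fewer reads. At a ratio of 1.5 there were 6 and 4. At 10 reads there were 4 and 2.

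The share of reads in the listed families was 1.88% in 3-79 and 1.33% in TM-1 with identical tags, 7.39% and 6.06% with 1 mismatch, 6.93% and 5.70% of reads of 18 to 26 nt, and 15.1% and 12.7% without tags of 1 read. The ratio of 24 nt to 21 nt reads was 5.48 and 5.85 for distinct tags, 2.36 and 2.62 without tags of 1 read, 5.43 and 5.71 without the 100 most abundant tags, and 3.45 and 3.77 without reads of the structural RNAs and adaptors searched. It stayed higher in TM-1 in each. The share of tags also seen in the other library was 28.7% and 28.5% without tags of 1 read, and 13.2% and 13.0% with TM-1 thinned. Tags at least 4-fold apart numbered 1502 in 3-79 and 1687 in TM-1 at 20 reads, and 3 and 5 at 1000 reads. The MYB list median turned to -0.16 with identical tags, where 1 member was left. The medians of the developmental list and of the families first described in cotton or rosids also turned, to -0.21 and -0.16 when scaled to the listed families, to -0.16 for the former with identical tags and to -0.12 for the latter with 1 mismatch. That last turn came with the entry of miR479, with 0 reads in 3-79 and 29 in TM-1. The auxin list median was -1.07 with identical tags. The disease resistance list median was -3.15 with 1 mismatch, which admits miR2118 with 0 reads in 3-79, and -1.85 with miR2118 at the floor of 3 counts. Of 199 log2 ratios of single families under the alternatives, 12 changed sign: 7 when scaled to the listed families and 1 by trimmed mean, each a constant shift of all families, and 4 with identical tags. Apart from the effects of fewer tags, members or families that the alternatives themselves impose, the cause was not tested. Of the 5 listed families, miR827 rests on the fewest reads in a library, 8 in TM-1.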

Other observations

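The tests of miR399 and miR827 against scaling, base differences and over-amplification, and the test of miR167 against sequencing error, were chosen after the result was seen; those of miR2111 and of the miR167 passenger strands were set before their values were seen.

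Some close relatives of miR172 and miR535, chosen after their values were seen, differed more between the libraries than these families did. The miR172-like tag AGAATCCTGATGATGCTGCAG, the T7C form of the miR172 tag AGAATCTTGATGATGCTGCAG, had 9236 reads in 3-79 and 3773 in TM-1, a ratio of 2.47 (2.38 to 2.57). The latter tag had 4216 and 2077 reads, a ratio of 2.05 (1.94 to 2.16), and the listed miR172 tag AGAATCTTGATGATGCTGCAT had 3826 and 5353, a ratio of 0.722 (0.692 to 0.752). The miR535-like tag TGACAATGAGAGAGAGCACGC, the C7T form of the listed miR535, had 622 and 2417 reads and was 3.85-fold higher in TM-1 (3.52 to 4.21), while the miR535 family had a ratio of 0.992 (0.921 to 1.07). With 1 mismatch allowed, which admits that tag, the family ratio was 0.536 (0.509 to 0.563). The miR172 passenger strand had 417 and 231 reads, a ratio of 1.82 (1.55 to 2.15). With identical tags its ratio was 0.505 (0.230 to 1.05) on 12 and 24 reads. The miR396 passenger strand had a ratio of 4.85 on 24 and 5 reads, but of 0.987 on 3747 and 3832 reads with 1 mismatch allowed.

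For the higher miR399 and miR827 in 3-79, the 4 scalings tried cannot account for log2 ratios of 2.78 and 4.39. Each shifts all families alike, the largest shift was -0.28, and the smallest log2 ratio was 2.50. A difference of 1 base in the mature sequence is argued against, since the smaller log2 ratio was 2.72 with 1 mismatch allowed. Forms that differ by more than 1 base within positions 3 to 18 were not searched and stay open. Over-amplification of 1 sequence is argued against as the whole cause for miR399, whose reads with the miR399b core had a log2 ratio of 1.55 (0.77 to 2.38), but stays open as a part of it: the most abundant tag had a ratio of 8.45 (6.49 to 11.2), the rest of the family 3.25 (2.09 to 5.21), and identical tags a log2 ratio of 0.52 (-0.64 to 1.71). For miR827 it cannot be told apart, since 161 of its 166 reads in 3-79 were 1 tag and only 6 reads in the libraries lay outside that tag. A phosphate-related difference between the fiber samples was a hypothesis that predicted at least 2-fold more miR2111, another phosphate-responsive family, in 3-79, but miR2111 had 35 and 37 reads, a ratio of 0.955 (0.584 to 1.56), a negative result. A difference between the species, or between the plants sampled, stays open.

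For the T21C form of miR167, abundant in TM-1 and rare in 3-79, sequencing error is argued against, since in TM-1 it was 109 times the next most frequent substitution at that position. A separate set of miR167 precursors active in TM-1 alone predicted a passenger strand nearly absent from 3-79, and the lowest ratio among 3 passenger forms was 0.567 (82 and 146 reads), which met the bound set in advance against that hypothesis. These forms held 590 of 1624 passenger reads in 3-79 and 365 of 746 in TM-1; a wider search, made after the values were seen, gave 7 forms with the same lowest ratio, of which 1 carried mismatches and had 57 and 61 reads. The bound was judged wrong after the value was seen, because the 3 forms are end variants of 1 sequence with 0 mismatches to the listed passenger strand, so precursors that share a passenger strand cannot be told apart. A sequence difference between the species in a miR167 gene stays open and was not tested without a genome.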
